A study of Pimephales promelas with 182 samples.

How the data were processed

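Ovary RNA of female fathead minnows was hybridised to Agilent arrays, with 1 array and 1 dye (Cy3) per sample, for 182 samples in 24 groups of exposure or recovery day and fadrozole dose. Per the labels, RNA was extracted with Qiagen RNeasy, and labelled RNA was made from 0.4 µg with Agilent's low-input linear amplification. The labels place each sample in its group by treatment, day and replicate number. They do not say that the arrays of a group came from separate fish, so p-values measure the spread between these samples, which may be technical.

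Per the file headers, the arrays were scanned on a GenePix 4000B scanner, and the authors made the intensity values with Feature Extraction 9.5.3.1, protocol GE1-v5_95_Feb07. The processed intensity is background-subtracted and detrended within the array, with a surrogate value for dim spots, and is not scaled between arrays, per the file headers. Each file held 15744 spots, of which 536 were controls and 15208 were probes of 60 bases in 1 layout. The authors' deposited value table holds the same processed intensity on a linear scale, not centred, equal within a relative difference of 1.2e-06, and it keeps spots with an outlier flag. All 182 of its columns were mapped to samples.

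Of the probes, 3309 are named in the files by a database number and 11899 by a contig, and 0 have a gene symbol. In the reference table used here (assembly fPimPro1.hap1.1), 0 of the identifiers matched. Gene lists fixed before the data were examined (steroid synthesis, egg envelope, cell type markers and others) were therefore not tested, and no genome coordinates are given.

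For the main setting, each array's 75th percentile of log2 processed intensity was subtracted. Control spots were left out, and spots with an outlier flag were set to missing, a median of 718 probes per array. Saturated spots, a median of 51.5 per array, were kept. A probe was tested where it was well above background in at least 0.5 of the arrays of at least 1 of the 24 groups, which left 13794 probes. Outlier flags can remove bright spots from most arrays of a group, and a difference then rests on few arrays. The dimmest and brightest arrays had a 75th percentile of 545.1 and 8429.5, and no pair of arrays held identical values.

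A model with a mean for each of the 24 groups was fitted over all arrays, with limma's moderated test (2-sided) and Benjamini-Hochberg adjustment within each comparison, called at an adjusted p under 0.05. Each dose was compared with water at each day, and as the mean over the 4 exposure days and over the 4 recovery days. Further contrasts set the 30 µg/L exposure effect against the recovery effect and the 30 µg/L effect against the 3 µg/L effect, and moderated F tests asked whether the 30 µg/L effect differed between days. The fits with slide or other terms used generalised least squares, exact for missing spots, with limma's variance moderation. The tests were checked on simulated data, in which labels were permuted within days and known changes were added to 200 probes of 13794.

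The probes named are the first by size of those called in each direction, by a rule fixed before the data were examined. That rule was written for gene names and was applied to probe IDs, with at most 2 of each direction per comparison. The probe that follows the called ones, other probes of 1 contig and the probes of the comparison of phases were chosen after their values were seen. Where a probe was not well above background on any array of a group, a fold is given as at least the brighter group's mean over the dim group's mean, taking on each array the higher of the lowest signal well above background and the probe's own.

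Slide (23 slides of 6 to 8 arrays, each with 4 to 8 groups) and scan day (4 days) were read from the files and tested as batches. The alternatives fixed in advance were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, no filter on dim probes, the authors' value table, array weights, slide as a random block, the replicate number as a block, and only the arrays of 1 day. Omission of single arrays was fixed for exposure day 1. Chosen after seeing the data were slide or scan day as a fixed term, slide with the most distant array left out, and omission of single arrays for the other comparisons. Each comparison was refitted on 100 splits of the same arrays within each day. The splits that involve 3 µg/L were also drawn without the array most distant from the others, chosen after seeing the data. The fits used R 4.3.3, limma 3.58.1 and the data.table package (1.17.8), and the files were read and plots drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.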

Results

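Ovary RNA of reproductively mature female fathead minnows (Pimephales promelas, a small freshwater fish used in toxicology) was measured on 182 Agilent arrays, with 1 array and 1 dye (Cy3) per sample. The fish had been held in water with fadrozole at 0, 3 or 30 µg/L. Fadrozole inhibits aromatase, the enzyme that turns androgens into estrogens. Ovaries were taken after 1, 2, 4 and 8 days of exposure and after 1, 2, 4 and 8 further days of recovery in clean water, which gives 24 groups of day and dose. The water group at exposure day 1 held 5 arrays and each other group 7 or 8. The series title puts the question as how aromatase inhibition, and the recovery from it, act on the ovary.

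Each array carried 15208 probes of 60 bases. The probes are given here by their IDs, because the files used here do not pair them with gene names. Between 59.8% and 94.7% of the probes of an array were well above background, with a median of 80.5%. The 75th percentile of the processed intensity ran from 545.1 to 8429.5, with a median of 1970.0. Levels below are log2 intensities relative to that percentile of the same array, so that 0 is the 75th percentile, and a fold compares geometric means. The number of arrays limits the precision. The median standard error over probes was between 0.32 and 0.38 log2 units for a comparison at 1 day, and 0.17 for the mean of the 4 exposure days at 30 µg/L.

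Over the 4 exposure days, 1 probe rose and 1 fell at 30 µg/L against water among 13504 tested. UF_Ppr_AF_106506 (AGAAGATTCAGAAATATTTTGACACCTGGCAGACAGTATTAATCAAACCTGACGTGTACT) rose (log2 difference 2.55, SE 0.37, adjusted p = 1.12e-06). It lay above the mean of the same day's water arrays in 28 of 29 arrays at 30 µg/L. Its signal was well above background on 26 of those 29 arrays and on 9 of the 28 water arrays, so the size of its differences from water rests largely on values near background. UF_Ppr_AF_116892 (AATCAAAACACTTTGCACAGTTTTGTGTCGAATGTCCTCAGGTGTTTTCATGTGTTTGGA) fell (log2 difference -1.68, SE 0.26, adjusted p = 5.53e-06) and lay below the day's water mean in 28 of 29 arrays.

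Both differences were present on single slides and within single scan days. On the 11 slides that held exposure arrays of both 30 µg/L and water, UF_Ppr_AF_106506 was higher at 30 µg/L on 10, and UF_Ppr_AF_116892 was lower on 11. With slide as a term in the fit, the log2 difference of UF_Ppr_AF_106506 was 2.68 (SE 0.38, adjusted p = 6.73e-07) and that of UF_Ppr_AF_116892 was -1.64 (SE 0.24, adjusted p = 1.07e-06). Within scan days 1, 2 and 3 the differences were 3.2, 3.0 and 1.7 for UF_Ppr_AF_106506, and -2.15, -1.30 and -1.68 for UF_Ppr_AF_116892. Scan day 4 held no exposure array of these doses. For both probes the size of the difference depended on the background correction. With normexp correction and quantile normalization it was 0.76 log2 units for UF_Ppr_AF_106506 (adjusted p = 3.67e-08) and -0.80 for UF_Ppr_AF_116892.

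**Figure D1:**
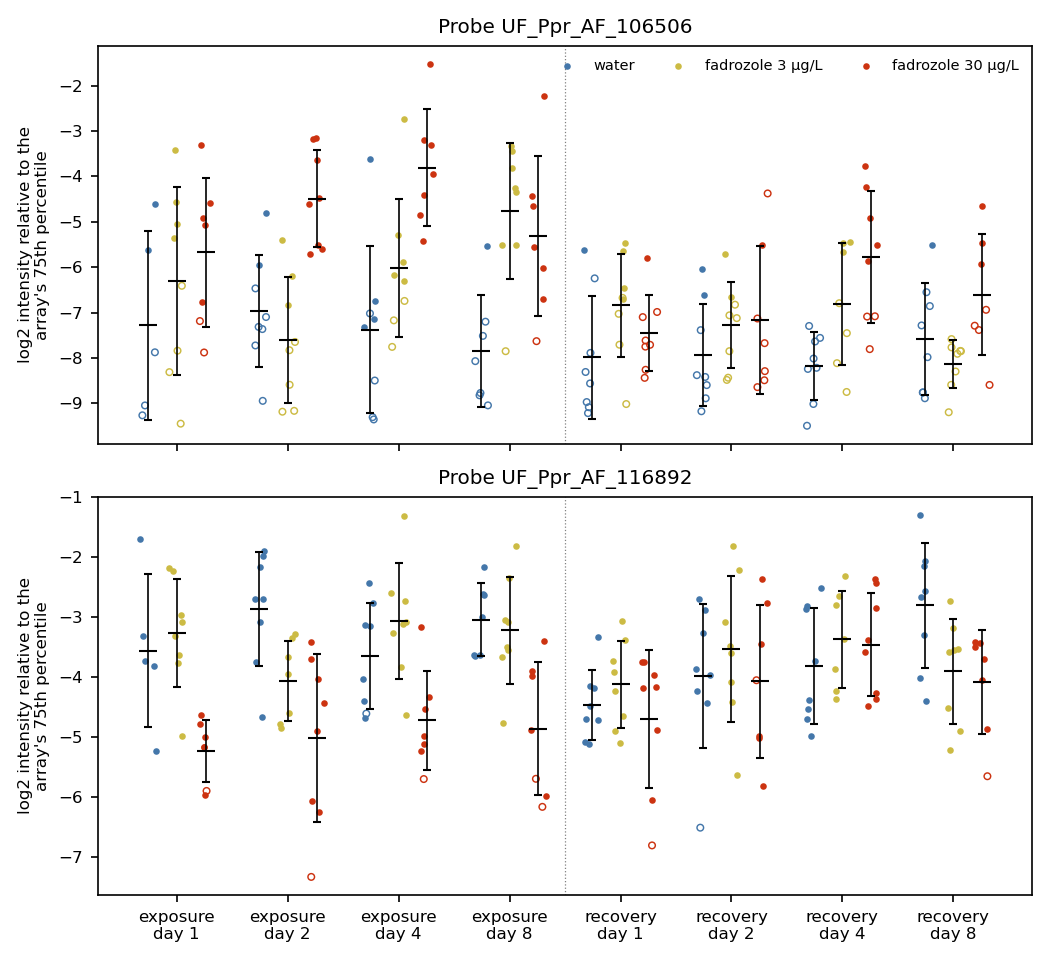
Log2 level relative to the array's 75th percentile (y axis) of UF_Ppr_AF_106506 and UF_Ppr_AF_116892 on each array, by day of exposure and recovery (x axis) and dose. Filled points are well above background and open points are not, and bars give the mean ± SD of each group. At exposure day 4 UF_Ppr_AF_106506 averaged -3.81 at 30 µg/L and -7.37 in water.

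By day, the difference in UF_Ppr_AF_106506 between 30 µg/L and water passed the threshold at exposure day 4. Its level there was -3.81 ± 1.29 (SD, n = 7) at 30 µg/L and -7.37 ± 1.84 (SD, n = 8) in water, a rise by 3.57 log2 units (SE 0.71, adjusted p = 0.0170). It was well above background on 4 of those 8 water arrays, and with normexp correction and quantile normalization the difference was 1.19 (adjusted p = 0.000118). Its log2 differences were 1.61 (SE 0.80) at day 1, 2.47 (SE 0.68) at day 2 and 2.54 (SE 0.73) at day 8, with adjusted p between 0.441 and 1.00. UF_Ppr_AF_116892 showed log2 differences of -1.67 (SE 0.56), -2.15 (SE 0.48), -1.07 (SE 0.50) and -1.82 (SE 0.51) at exposure days 1, 2, 4 and 8, none past the threshold at a single day. The day 4 call was lost with slide as a term (log2 difference 3.27, adjusted p = 0.224), with array weights (adjusted p = 0.151) and with only the arrays of that day (adjusted p = 0.524). It was also lost without water replicate 4, 6 or 7 or 30 µg/L replicate 3, 4 or 6 (log2 difference 3.18 to 3.48, adjusted p = 0.0756 to 0.341), and without water replicate 2 the difference was 4.10 and 2 probes were called.

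At exposure day 8 the probe called at 30 µg/L was UF_Ppr_AF_115400, which was 2.28-fold higher than in water (log2 difference 1.19, SE 0.23, adjusted p = 0.0128). Its mean was 2.55 ± 0.27 (SD, n = 7) at 30 µg/L and 1.36 ± 0.37 in water (SD, 6 of 7 arrays without an outlier flag), while the means of the other 23 groups lay between 2.03 and 2.68. On the same day its difference at 3 µg/L was 1.09 (adjusted p = 0.0691). The call was lost with slide as a term (log2 difference 1.12, adjusted p = 0.329), under both other normalizations and in the authors' value table. It was also lost without water replicate 1, 2 or 3 or 30 µg/L replicate 1, 5 or 6 (log2 difference 1.17 or less, adjusted p = 0.0563 to 0.191).

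At exposure days 1 and 2, limma called 0 probes at 30 µg/L against water, with 220 and 819 probes at an unadjusted p under 0.05. Here 13537 and 13710 probes were tested, and a share of about 0.05 would be expected with no change. Unadjusted counts near or below that share, here and in the other comparisons, show no response by themselves. The test of whether the 30 µg/L effect differed between the 4 exposure days called 0 probes, with 705 at an unadjusted p under 0.05. In simulated data of the same size, 36.1% of 2-fold and 77.8% of 4-fold changes were recovered at day 1. At day 2 the shares were 50.5% and 86.9%, but 364 unchanged probes were called as well. Other splits of the day 2 arrays at 30 µg/L and in water called at most 6 probes. So many false calls loosen the adjusted cut-off, so the day 2 shares do not give the sensitivity of the real comparison. The simulated labels were permuted over all doses of a day, so arrays of 3 µg/L could fall in either group. This includes replicate 7 of 3 µg/L at exposure day 2, described below, which the real comparison and its splits do not hold. Whether that array gave the 364 was not tested. For the mean of the exposure days, 83.5% of 2-fold and 98.0% of 4-fold changes were recovered.

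After the return to clean water, limma called 0 of 13528 probes for the mean of the recovery days at 30 µg/L, with 1043 at an unadjusted p under 0.05. UF_Ppr_AF_116892 then differed from water by -0.31 log2 units (adjusted p = 0.734). UF_Ppr_AF_106506 did not pass the threshold either (adjusted p = 0.645), though 24 of 30 arrays at 30 µg/L lay above the day's water mean. No size is given for it, since its water signal was mostly at background. UF_Ppr_AF_106506 was well above background on 10 of 30 arrays at 30 µg/L and on 4 of 32 water arrays in recovery. At recovery day 4 UF_Ppr_AF_106506 was not well above background on any of the 8 water arrays, and its mean at 30 µg/L was at least 2.83-fold higher (adjusted p = 1.00). The test of exposure effect against recovery effect at 30 µg/L called 0 probes, with 461 at an unadjusted p under 0.05. The difference of effects was -1.37 (adjusted p = 0.546) for UF_Ppr_AF_116892, and for UF_Ppr_AF_106506 the adjusted p was 0.999, so neither probe was shown to respond differently in the exposure and recovery phases.

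At recovery day 2, UF_Ppr_AF_107984 was 2.74-fold higher at 30 µg/L than in water (log2 difference 1.45, SE 0.30, adjusted p = 0.0490). Its mean was -1.98 ± 0.77 (SD, n = 7) at 30 µg/L, -2.46 ± 0.73 (SD, n = 8) at 3 µg/L and -3.43 ± 0.61 (SD, n = 8) in water. This call held in 2 of 11 alternative settings, with log2 differences of 1.07 to 1.51 and adjusted p between 0.00910 and 0.920, and was kept only without water replicate 1 or 7 or 30 µg/L replicate 2 or 5 among the 15 single-array omissions (log2 difference 1.31 to 1.66). At recovery days 1, 4 and 8 limma called 0 probes, with 594, 432 and 1071 at an unadjusted p under 0.05. The 30 µg/L effect differed between recovery days for 0 probes, with 676 at an unadjusted p under 0.05. This count rose with slide as a term and without replicate 7 of 3 µg/L at exposure day 2, as given in the part on processing. That array stayed in the shared fit of the 30 µg/L comparisons with water, and their counts were not taken without it alone.

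At 3 µg/L, 400 probes were called against water at exposure day 2, of which 37 were higher and 363 lower. The array of replicate 7 of that group decided this count. Its correlation with the mean profile of the arrays was 0.624, while the next lowest of all arrays was 0.953 and the median 0.974. Of the 400 probes, 390 were measured on it, and the probes called lower lay a median of -4.55 log2 units from the other arrays of the group there. Without it limma called 0 probes, with 765 at an unadjusted p under 0.05. The first probe of the rise by size was UF_Ppr_AF_102810 (log2 difference 2.84, SE 0.84, adjusted p = 0.0381, n = 8 and 8), and its difference without that array was 2.25 (adjusted p = 0.857). The first of the fall was UF_Ppr_AF_110043 (log2 difference -5.76, adjusted p = 5.00e-10), which rested on that array alone among the 8, since the other 7 spots carried an outlier flag.

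**Figure D2:**
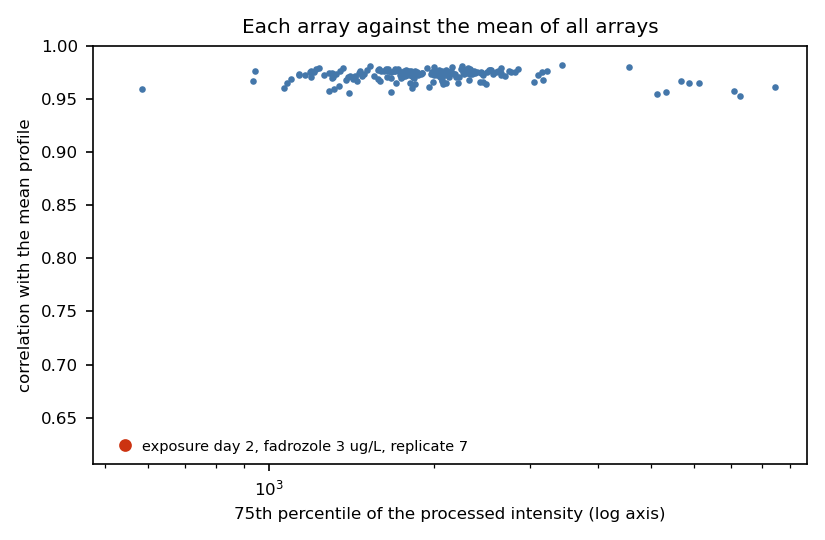
Correlation of each of the 182 arrays with the mean profile of all arrays (y axis, starting above 0) against the array's 75th percentile of processed intensity (x axis, log scale), 1 point per array. The array of 3 µg/L, exposure day 2, replicate 7 lies at 0.624 and all other arrays at 0.953 or higher.

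The other comparisons of 3 µg/L with water gave few calls or none. At exposure days 1, 4 and 8 limma called 0 probes, with 189, 444 and 774 at an unadjusted p under 0.05, and without the array that stood apart 2 probes were called at day 8. The mean over the exposure days gave 3 probes, of which UF_Ppr_AF_100101 was higher (log2 difference 0.99, SE 0.22) and UF_Ppr_AF_118327 (-0.85, SE 0.15) and UF_Ppr_AF_102163 (-0.82, SE 0.16) were lower, each at adjusted p = 0.0483. UF_Ppr_AF_100101 was called in 0 of 10 alternative settings and 15 of 60 single-array omissions, and UF_Ppr_AF_102163 in 0 of 8 settings. In exposure UF_Ppr_AF_100101 was well above background on 24 of 32 arrays at 3 µg/L and 11 of 28 in water, so its size rests partly on values near background. For UF_Ppr_AF_118327 and UF_Ppr_AF_102163, 8 of the 32 arrays at 3 µg/L had no outlier flag, and at exposure day 2 the only one was replicate 7, the array that stood apart. It lay at 0.07 and -0.74 there, against water means of 3.38 and 1.84, so most of both differences rests on it, and without it neither has a value. Without that array UF_Ppr_AF_100101 differed by 0.91 (adjusted p = 0.505), and limma called 0 probes, with 667 at an unadjusted p under 0.05. UF_Ppr_AF_106506 differed from water at 3 µg/L by 1.2 log2 units over the exposure days (SE 0.36, adjusted p = 0.57), with 22 of 32 arrays above the day's water mean, and by 3.09 at exposure day 8 (SE 0.71, adjusted p = 0.102). UF_Ppr_AF_116892 differed by -0.13 (SE 0.25, adjusted p = 0.893). In recovery at 3 µg/L limma called 0 probes at days 1, 2, 4 and 8, with 296, 799, 325 and 958 at an unadjusted p under 0.05, and 0 for their mean, with 123.

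The effects of the doses over the exposure days differed for 7 probes among 13594 tested, 5 with a higher value at 30 µg/L than at 3 µg/L and 2 with a lower one. UF_Ppr_AF_116892 was lower at 30 µg/L than at 3 µg/L (log2 difference -1.55, SE 0.25, adjusted p = 4.93e-05; -1.81 to -0.69 over the alternative settings). UF_Ppr_AF_113667 was lower too (log2 difference -0.98, SE 0.17, adjusted p = 0.000360; -1.02 to -0.55 over the settings). It lay below the day's water mean on 24 of 29 arrays at 30 µg/L and above it on 23 of 32 arrays at 3 µg/L. UF_Ppr_AF_115622 was higher at 30 µg/L (log2 difference 1.45, SE 0.31, adjusted p = 0.0213; 0.47 to 1.62 over the settings), and was well above background on 26 of 29 arrays at 30 µg/L and 19 of 32 at 3 µg/L. This call held in 8 of 10 settings (adjusted p up to 0.0759) and was lost without 30 µg/L replicate 2 of exposure day 1 (log2 difference 1.37, adjusted p = 0.0578). For UF_Ppr_AF_106506 the difference between the doses was 1.35 (SE 0.35, adjusted p = 0.129). Without replicate 7 of 3 µg/L at exposure day 2 the count was 5, with 3 higher and 2 lower. The count was 3 without 30 µg/L replicate 2 of exposure day 1, and between 11 and 17 without 30 µg/L replicate 3 or 3 µg/L replicate 1, 2, 4, 5 or 8 of exposure day 2.

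Across all probes, the log2 differences of both doses from water over the exposure days correlated with r = 0.26 (covariance 0.0144), without the array that stood apart. Probes are not independent replicates, and both differences use the same water arrays. In 50 permutations of the dose labels within days, which keep a shared water group, the mean r was 0.50, between -0.20 and 0.75, with a mean covariance of 0.0236. With the water arrays split between the doses, in 25 splits, the median r was -0.073 and the median covariance -0.00549. For recovery the observed r was 0.41 (covariance 0.0163), the mean permuted r 0.49 (covariance 0.0192), and the median r with split water arrays 0.0052 (covariance 0.000295). The resemblance of the doses across all probes was thus no larger than permuted labels with a shared water group gave.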

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

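The splits of the arrays within each day were set before the data were examined, and those without the array that stood apart were chosen after the results were seen. The tests of explanations were chosen after the results they bear on had been seen, and what each test, the splits included, would show was written down only afterwards.

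The array of 3 µg/L, exposure day 2, replicate 7 lay far from the others of its group, with a profile correlation of 0.624 and 0.958 for the nearest. The lowest correlation among the next 10 dimmest arrays was 0.959, which argues against low brightness alone. Its 10 spike-in controls correlated at 0.990 with their medians on the other arrays. The lowest other array reached 0.956 and the median of the others was 0.995. This argues against failed labelling, hybridisation or scanning as the whole cause. Spike-in controls do not measure the sample's own RNA, so the quality of that RNA was not tested. On it 967 probes lay at least 4-fold above their level on all other arrays, against at most 7 on any other array, so a candidate explanation is RNA of other content. Whether that RNA came from another tissue, another species or a mixed sample was not tested, and an effect of the dose in a single fish stays open.

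UF_Ppr_AF_106506 and UF_Ppr_AF_116892 were called at 30 µg/L over the exposure days. With slide as a fixed term their log2 differences were 2.68 and -1.64, which argues against slides as the cause. The smallest differences over the omissions of 1 array were 2.42 and -1.56 (largest adjusted p = 1.23e-05 and 7.80e-05), so no single array carries them. The smaller differences under the other normalizations were 0.76 and -0.80, past the threshold but less than the 2.55 and -1.68 of the main setting, and quantile normalization alone gave 2.55 and -1.59, so the sizes depend on the background correction. A response of these transcripts to fadrozole is a hypothesis consistent with these values.

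Over all doses, 1034 probes differed between the recovery and the exposure phase, 831 higher and 203 lower in recovery, without the array that stood apart, and the highest other of 35 splits of the 8 sampling days into equal sets gave 498. With slide as a fixed term 121 probes were called, 42 higher and 79 lower, and 54 were called both ways in the same direction. Among the same 35 splits, 5 called as many as 121 with the slide term, the real one included, and the highest other called 547, so another grouping of the days could give the count. With the slide term 998 of the 1034 kept their direction, while their median size fell from 0.33 to 0.15 log2 units and their median SE was 0.094 and 0.085, so calls were lost to smaller differences and slides may carry part of them. A change with age, season or time in clean water stays open and was not tested.

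Other arrays lay far from the rest of their group in profile correlation: 0.966 for 3 µg/L at exposure day 1, replicate 7 (nearest 0.973), and for 30 µg/L 0.957 at exposure day 8, replicate 2 (nearest 0.976), 0.960 at recovery day 1, replicate 5 (nearest 0.972), 0.953 at recovery day 2, replicate 2 (nearest 0.969) and 0.955 at recovery day 4, replicate 5 (nearest 0.971). Of these, the arrays of exposure day 8, recovery day 2 and recovery day 4 lay on slide 8, whose 8 arrays of all doses had the 75th percentile at 5129.1 to 8429.5 and profile correlations of 0.953 to 0.967. Of 48 group values tested, 7 had such an array, and chance alone gives about 1 in 20. The level of UF_Ppr_AF_106506 in water at exposure day 4, replicate 2 was -3.62, with the nearest at -6.75, and without this array the difference of 30 µg/L from water was 4.10 and not 3.57. The effects of the doses over the exposure days differed for 7 probes, by a test of the difference itself.

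For the 2 probes called at 30 µg/L over the exposure days, only the real split of the 100 gave as many, and the highest other gave 1. This is the lowest share that 100 splits can give. With 24 comparisons, and with the probes filtered under the real groups, the splits alone do not exclude chance for this count. The single calls at exposure days 4 and 8 were matched by 3 of 100 splits each, the real one included, with a highest other of 1. Splits were drawn for 24 comparisons, among which shares this low can arise by chance. Chance is therefore not excluded for these single calls, and both were lost with slide as a fixed term. Chance cannot be excluded for the single call at recovery day 2 (10 of 100 splits, highest other 53), the 7 probes between the doses (11 of 100, highest other 254), the 400 probes at 3 µg/L and exposure day 2 (24 of 100, highest other 1225) or the 3 probes of the 3 µg/L exposure mean (48 of 100, highest other 207). These last 3 results include the array that stood apart, which moves between groups in the splits. Without it 5 probes were called between the doses, by only the real split of 100 (highest other 3). This rerun was chosen after the results were seen, and all splits kept the probes that passed the filter under the real groups. It therefore does not exclude chance for that count. UF_Ppr_AF_116892 and UF_Ppr_AF_113667 were called between the doses in 10 of 10 alternatives and 61 of 61 omissions, and of the higher ones UF_Ppr_AF_115622 in 8 of 10 and 60 of 61 and UF_Ppr_AF_104165 in 9 of 10 and 58 of 61. In exposure UF_Ppr_AF_104165 was well above background on 14 of 29 arrays at 30 µg/L, 4 of 32 at 3 µg/L and 3 of 28 in water. Its log2 difference of 1.40 (0.31 to 1.57 over the alternatives) thus rests largely on values near background. Without the array that stood apart, limma called 0 probes at 3 µg/L at exposure day 2 and for the exposure mean (765 and 667 unadjusted), with a highest other of 2 and 3. The array is not part of 3 µg/L at exposure day 8, but enters the spread, and without it 2 probes were called there and not 0. For these 2, 4 of 100 splits gave as many, the real one included, and the highest other gave 68. The array was left out after the results were seen, so this share does not exclude chance.

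For every comparison in which limma called 0 probes, 100 of 100 splits gave as many, as they must. The highest other split at 30 µg/L gave 1 and 6 probes at exposure days 1 and 2, 1, 0 and 6 at recovery days 1, 4 and 8, 1 for the recovery mean, 501 for exposure against recovery, and 3 and 2 for the differences between exposure days and between recovery days. For 3 µg/L it gave 1, 3 and 1 at exposure days 1, 4 and 8, 24, 368, 1 and 49 at recovery days 1, 2, 4 and 8, and 13 for the recovery mean. The splits with 368 and 501 probes point to a structure of the samples, and what they separate was not tested. In the splits drawn anew without the array that stood apart, the highest at 3 µg/L was 15 at recovery day 2, 412 at exposure day 1 and 157 at recovery day 8, so the highest count changed with the draw or with the spread. The unadjusted counts of these comparisons lay between 123 and 1071.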

How the results depend on the processing

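Slide or scan day as a fixed term, slide with the array that stood apart left out, and single omissions outside exposure day 1 were chosen after the data were seen. Gene lists were not tested under any alternative, since the files used here do not pair probes with genes. Of 256 counts under alternatives other than omissions, 64 lay further than 1.5 times from the main count, and of 783 counts with 1 array omitted 104 did. Of 794 values of named probes, 554 kept direction and call, 239 kept direction and lost the call, and 1 changed sign. UF_Ppr_AF_106506 and UF_Ppr_AF_116892 over the exposure days at 30 µg/L were called in 10 of 10 alternatives and 57 of 57 omissions each. Signal over background limits UF_Ppr_AF_106506, which was well above it on 9 of 28 water arrays in exposure. Except where fewer arrays, an omitted array or a low array weight gives it, the cause of the changes below was not tested. Counts of 0 are from limma.

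Normexp correction with quantile normalization gave 1 call at 30 µg/L recovery day 1 (main count 0), 0 at recovery day 2 (main 1), 1 for the recovery mean (main 0), 2, 1 and 1 for 3 µg/L at exposure days 4 and 8 and recovery day 1 (main 0 each), 1 for the 3 µg/L exposure mean (main 3) and 17 between the doses (15 higher and 2 lower, main 7 with 5 and 2). Quantile normalization alone gave 0 at 30 µg/L exposure day 8 (main 1) and recovery day 2, 4 for the 30 µg/L exposure mean (main 2) and 1 for the 3 µg/L exposure mean. No filter on dim probes gave 0 at 30 µg/L recovery day 2 and 0 for the 3 µg/L exposure mean. The authors' value table gave 0 at 30 µg/L exposure day 8 and recovery day 2, 1 at 3 µg/L exposure day 1 and 0 for the 3 µg/L exposure mean, where UF_Ppr_AF_102163 turned from -0.82 to 0.055.

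Array weights gave 3, 0 and 1 at 30 µg/L exposure days 2 and 4 and recovery day 4, 9 for the exposure mean and 1 for exposure against recovery. For 3 µg/L they gave 0 at exposure day 2, 10 at exposure day 8, 1 at recovery day 1 and 0 for the exposure mean, and 36 between the doses. The weight of 3 µg/L replicate 7 at exposure day 2 was 0.034, so this fit nearly left that array out. Its omission also gave 0 at 3 µg/L exposure day 2. Slide as a random block gave 0 at 30 µg/L recovery day 2, 2 at 3 µg/L exposure day 8, 0 for the 3 µg/L exposure mean and 13 between the doses. Slide as a fixed term gave 0 at 30 µg/L exposure days 4 and 8 and recovery day 2, 1 for the recovery mean and 1 for exposure against recovery. It gave 15, 2 and 0 at 3 µg/L for exposure days 2 and 8 and the exposure mean, and 11 between the doses. Scan day as a fixed term gave 5, 1 and 0 at 3 µg/L for exposure day 8, recovery day 2 and the exposure mean. Only the arrays of that day gave 0, 2 and 0 at 30 µg/L exposure days 4 and 8 and recovery day 2, and 0 at 3 µg/L exposure day 2, with fewer arrays to estimate the spread.

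Slide as a fixed term without the array that stood apart gave 0, 0, 2 and 2 at 30 µg/L exposure days 4 and 8 and recovery days 2 and 8, 1 for the recovery mean, 1 for exposure against recovery and 41 for the difference between recovery days (main 0). For 3 µg/L it gave 0, 2 and 0 for exposure days 2 and 8 and the exposure mean, and 3 between the doses.

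The replicate number as a block gave 1 and 0 at 30 µg/L exposure day 2 and recovery day 2, 256 at 3 µg/L exposure day 2, 0 for the 3 µg/L exposure mean and 2 between the doses, and moved no other count by over 1.5 times. Same-numbered arrays did not deviate together: the mean correlation of their residuals was 0.0046 over 174 pairs (lowest -0.41, 46 pairs over 0.1), and 23 arrays correlated best with one of their own number. These values thus showed no pairing of arrays by number, but they cannot exclude a weak one. Arrays of 1 slide correlated at 0.19.

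With 1 array omitted in turn, counts ranged at 30 µg/L from 0 to 2 at exposure day 2, 0 to 2 at day 4, 0 to 1 at day 8, 0 to 1 at recovery day 2, 2 to 4 for the exposure mean and 0 to 1 for exposure against recovery. The 4 came without water replicate 1 of exposure day 1 or 30 µg/L replicate 7 of exposure day 8. The highest counts came without 30 µg/L replicate 7 at exposure day 2, without water replicate 2 at day 4, and without 30 µg/L replicate 4 of recovery day 2 for exposure against recovery. At 3 µg/L they ranged from 0 to 1006 at exposure day 2, 0 to 1 at day 4, 0 to 3 at day 8, 0 to 1 at recovery days 1 and 2, and 0 to 7 for the exposure mean, and between the doses from 3 to 17. The highest counts came without 3 µg/L replicate 8 at day 4, without water replicate 6 or 3 µg/L replicate 4 at day 8, without 3 µg/L replicate 7 at recovery day 1, and without 3 µg/L replicate 3 or 7 at recovery day 2. The 7 came without 3 µg/L replicate 8 of exposure day 2, and the 17 without replicate 5 of that group. At 3 µg/L exposure day 2 the count was 0 without replicate 7, 36 without water replicate 1, 645 without water replicate 5 and 685 to 1006 without any other replicate of that group. At exposure day 1 the planned omissions gave 0 throughout for both doses.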

Other observations

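The probes and tests in this part were chosen after the values had been seen.

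The probe next in line after the called ones at 30 µg/L over the exposure days was UF_Ppr_AF_117212. Its mean level in exposure was -5.67 ± 1.36 (SD, n = 28) in water, -4.71 ± 1.96 (n = 32) at 3 µg/L and -3.52 ± 2.27 (28 arrays without an outlier flag) at 30 µg/L. The difference of 30 µg/L from water was 2.03 log2 units (SE 0.45, adjusted p = 0.0653), and with slide as a fixed term 2.3 (adjusted p = 0.0105). In recovery its mean was -5.73 ± 1.21 in water (n = 32), -6.49 ± 1.66 at 3 µg/L (n = 31) and -6.34 ± 2.19 at 30 µg/L (n = 30). The difference between the exposure and recovery effects was 2.65 (SE 0.62, adjusted p = 0.480).

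Over all doses, UF_Ppr_AF_102032 was higher in recovery by 0.60 log2 units (SE 0.09, adjusted p = 5.33e-06) and by 0.59 with slide as a fixed term (adjusted p = 0.000742), with 0.74 in water, 0.64 at 3 µg/L and 0.42 at 30 µg/L. UF_Ppr_AF_117212 was lower in recovery by -1.53 log2 units (SE 0.25, adjusted p = 1.44e-05), with -0.12 in water, -1.71 at 3 µg/L and -2.77 at 30 µg/L. In recovery it was well above background on 23 of 32 water arrays, 12 of 31 at 3 µg/L and 15 of 30 at 30 µg/L. The sizes of its falls thus rest partly on values near background. The test of 30 µg/L against water for the change between phases takes the opposite direction, exposure minus recovery. It gave the 2.65 above for UF_Ppr_AF_117212, not past the threshold, and 0.32 for UF_Ppr_AF_102032 (adjusted p = 0.999). Neither probe was thus shown to change between phases differently at 30 µg/L than in water.

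UF_Ppr_AF_116892 shares its contig family name with 6 other probes of the array. Their log2 differences at 30 µg/L over the exposure days lay between -0.69 and 0.15, with adjusted p = 1.00 for each. Whether these probes match the same transcript was not tested.

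A response shared by the days across all probes would make the log2 differences of separate days resemble each other. The mean correlation over the 6 pairs of days, across probes, was 0.069 for 30 µg/L in exposure, and 18 of 100 labelings within the days gave one as high (highest 0.212). It was 0.068 for 30 µg/L in recovery (18 of 100, highest 0.158), 0.079 for 3 µg/L in exposure (19 of 100, highest 0.345) and -0.071 for 3 µg/L in recovery (90 of 100, highest 0.190). These values leave open whether such a shared response was present, and the array that stood apart was left out.

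The first principal component of 181 arrays, without the array that stood apart, held 20.3% of the variance and the second 5.32%. Slide accounted for a share of 0.902 of the first component (permutation p = 0.001, the smallest the permutations give), the 24 groups for 0.159 (permutation p = 0.18) and the dose for 0.0317 (permutation p = 0.052). Across probes, its weights correlated with GC content at -0.47, over a GC range of 23.3% to 61.7%, and with mean level at 0.59.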
